A study of Mus musculus with 12 samples.

How the data were processed

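RNA was measured in 12 libraries of EpCAM-positive mouse liver cells described in the labels as cholangiocytes, the epithelial cells that line the bile ducts. The mice carried AlbCreERT2, a tamoxifen-dependent Cre recombinase under the albumin promoter, and Confetti, a reporter that turns on 1 of several fluorescent proteins after recombination. Tamoxifen was given on postnatal day 1. The 6 ConfettiPos libraries were made from reporter-positive cells and the 6 ConfettiNeg libraries from reporter-negative cells, as the titles name them. How the cells were sorted and gated is not given in the sources used here. RNA was extracted with a micro-scale column kit and amplified with a SMART-Seq template-switching kit, per the labels' protocols.

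The deposited table holds whole-number read counts per gene, not normalized, for 54513 gene names and all 12 libraries, and every value column was tied to a library. Reads were trimmed with Trim Galore and aligned with STAR 2.7.6a, per the submitters' processing notes. Read pairs were counted per gene name with featureCounts 2.0.1 against GENCODE M29, per the file headers. Both ends had to map, chimeric pairs were left out, at least 10 bases had to overlap, and strand was not used, per the file headers. GENCODE M29 annotates the mouse build GRCm39, and the coordinates printed are those of the deposited table. The submitters' processing notes list the human build GRCh38 instead, which contradicts the file header and the mouse gene names. The header names of the columns use EpcamNeg and EpcamPos where the sample titles use ConfettiNeg and ConfettiPos. The titles were followed. Because strand was not used, a gene and its overlapping antisense partner cannot be told apart. Reads that map to several places were not counted by default, so near-identical paralogs such as Lilrb4a and Lilrb4b, the Serpina1 genes, the globin genes and the immunoglobulin genes are uncertain.

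Depth ran from 24589341 to 38964307 counts per library. As a measure of depth, 3 counts in a library corresponded to 0.0776 to 0.117 CPM, the usual unit of counts relative to the scaled library total. Fold changes against undetected genes were computed with a floor of 3 counts summed over the 6 libraries of a group, and no fold was computed against a floor per library. Floors and counting intervals cover counting error only, since the reads carry no molecular identifiers and PCR copies are not independent molecules. Same-group libraries were compared for duplicates by chi-square over genes with at least 20 summed counts. The chi-square per degree of freedom ran from 16.8 to 134, so no pair agreed within sampling noise. Pearson correlations of log2 CPM between same-group libraries ran from 0.917 to 0.979.

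Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its defaults (a minimum count of 10 and a minimum total of 15), which left 15489 genes holding at least 99.8% of the counts of each library. Libraries were scaled by TMM. ConfettiPos was compared with ConfettiNeg by the robust quasi-likelihood F-test, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Adjusted p-values of genes come from this test unless another is named. Standard errors (SE) of log2 fold changes were taken as the fold change divided by the square root of F. Group values are means ± SD of CPM over 6 libraries.

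Before the data were examined, 19 pathway lists and 9 cell type lists were written. Calls within a list are given over all genes tested and, where that differs, adjusted over the list alone. Lists with at least 5 tested genes were tested with camera in limma 3.58.1, with a preset inter-gene correlation of 0.01 and again with a correlation estimated per list, and with fry. The mean log2 CPM of each list, with a prior count of 1, was compared between groups by an exact two-sided permutation test over the 924 assignments of the 12 libraries, with Benjamini-Hochberg adjustment over the 28 lists. The smallest p it can give is 0.00216. An exact sign-flip test of the 6 differences within mice, adjusted in the same way, was the paired form of it. The lists of extrahepatic duct and of pancreas and intestine genes were written after the main results had been seen.

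The genes named were chosen by a rule written before the data were examined. It took the 12 higher and the 12 lower genes with the smallest p among those past the threshold and changed at least 2-fold, predicted genes left out. It added up to 4 members of each list with the smallest p, and always Alb, Epcam, Krt19, Krt7, Sox9, Hnf4a, Spp1, Cdh1, Ptprc and a gene that is not reported here. Other genes named below were chosen after their values were seen and are identified as such.

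The file headers name Mouse 1 to Mouse 6 for the replicate numbers in both groups, so the numbers pair the libraries by animal. Xist and 4 Y-linked genes gave the same sex for both libraries in 6 of 6 mice, with 3 mice of each sex. The correlation of the deviations from the group means between the libraries of a mouse ran from -0.28 to 0.57 and was above 0.1 in 4 of 6 mice. The main test was fixed without the animal as a block, and the blocked fit was an alternative.

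Alternatives written before the data were examined were DESeq2 size factors, upper quartile scaling, no filter, a stricter filter, DESeq2 1.42.0, limma voomWithQualityWeights, non-robust dispersion, a fold threshold in glmTreat, the animal block, and leaving out each library. For the list levels, other prior counts and the median of the list were tried. After the data were examined, 3 more were added. These left out 4 libraries, used as a covariate the slope of each library's log2 expression on the GC content of the first 200 bases of transcripts, or used that covariate with the block. The sign-flip test had been planned for the hepatocyte secreted protein and biliary levels and was extended to the other lists. GC content came from GENCODE M21 transcripts matched by gene symbol, and no coordinate of that GRCm38 annotation was used. The gene 4933401J01Rik starts at 3143476 in the deposited table and at 3073253 in GENCODE M21.

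The scripts were tested on simulated counts for the comparison of 6 ConfettiPos with 6 ConfettiNeg libraries. Of 15489 genes, edgeR called 29.9% of 67 genes changed 1.5-fold, 55.2% of 67 changed 2-fold and 89.4% of 66 changed 4-fold, with 8 false calls among 124. Camera called 2 of 2 changed lists and 0 of 20 random lists. The simulated genes were drawn independently of each other and without an effect of the mouse. The simulation therefore cannot show how camera with the preset correlation behaves on genes that vary together. Antigen presentation, with an estimated correlation of 0.801, is such a list.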

Results

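Gene expression was compared between reporter-positive (ConfettiPos) and reporter-negative (ConfettiNeg) EpCAM-positive cholangiocytes from the livers of 6 mice, with 1 library of each kind per mouse. The reporter marks cells, and descendants of cells, in which the albumin promoter drove Cre at the time of tamoxifen on postnatal day 1. The series title speaks of hepatocyte-primed biliary epithelial cells, and the comparison asks how traced biliary cells differ from untraced ones. Total counts ran from 26787103 to 33711738 in the ConfettiNeg libraries and from 24589341 to 38964307 in the ConfettiPos libraries. Genes with at least 10 counts numbered 15060 ± 278 in ConfettiNeg and 16330 ± 404 in ConfettiPos (SD, n = 6 each, exact permutation p = 0.00216, adjusted p = 0.0151 over 7 library measures). That test leaves the pairing by mouse unused, and the library measures were not tested in paired form.

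ConfettiPos and ConfettiNeg libraries shared high expression of the biliary gene Spp1 but differed in several groups of genes. Macrophage markers were higher in ConfettiPos in 16 of 16 tested genes, with a median log2 fold change of 9.92, and dendritic cell markers in 9 of 9. Of the hepatocyte secreted protein genes, 31 of 37 were higher in ConfettiPos, among them Trf and Apob. Of the biliary identity genes, 18 of 36 were lower in ConfettiPos, including Krt19, Krt7 and Cldn7, and Car4 and Msln were lower as well. In all, 2076 of the 15489 genes tested were higher and 1661 were lower in ConfettiPos by edgeR. At least 2-fold changes made up 1255 of the higher and 379 of the lower genes. The libraries of the groups did not overlap in 1127 of the higher and 857 of the lower genes. These genes were called for differing between the groups, so this describes them and is no separate support. Chance gives 0.22% only for genes not chosen in this way. Of the higher genes, 779 (37.5%) had a mean under 1 CPM in ConfettiNeg. The first principal component held 53.3% of the variance and separated the groups. With a fold threshold in glmTreat, 1047 genes were higher and 372 lower.

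**Figure D1:**
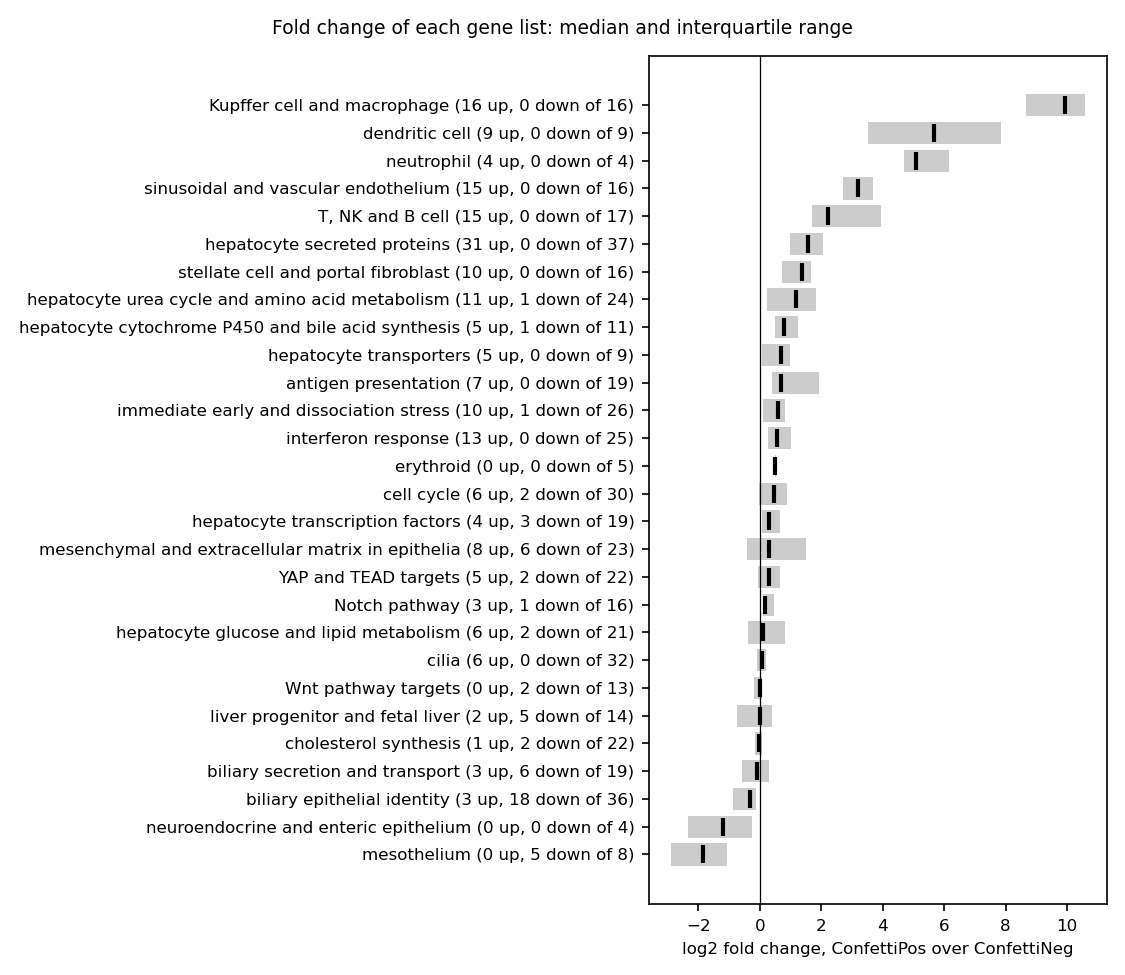
Log2 fold change of ConfettiPos over ConfettiNeg for the 28 gene lists, with the median as a black tick and the interquartile range of the tested members as a grey bar, and the counts of called genes beside each name. The macrophage list has the highest median, 9.92, and the mesothelium list the lowest, -1.86.

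The hepatocyte secreted proteins, plasma proteins made by the liver, were higher in ConfettiPos in 31 of 37 tested genes and lower in 0 (33 and 0 adjusted over the list alone). Trf, the gene of the iron carrier transferrin (chromosome 9, 103081200 to 103107643), rose from 452 ± 117 to 1207 ± 205 CPM (SD, n = 6, log2 fold change 1.42, SE 0.16, edgeR adjusted p = 2.12e-05). Apob, of the main protein of very low density lipoprotein, rose from 79.9 ± 24 to 196 ± 13.3 CPM, and Hp, of haptoglobin, from 1.73 ± 0.93 to 12.4 ± 4.2 CPM. Alb, whose promoter drives the Cre (chromosome 5, 90608756 to 90624461), was at 881 ± 215 CPM in ConfettiNeg and 1258 ± 95.7 CPM in ConfettiPos (log2 fold change 0.51, SE 0.13, edgeR adjusted p = 0.0104). The Alb call was lost when 4 libraries were left out (adjusted p = 0.0658, with adjusted p from 0.000123 to 0.0658 over its alternatives). The mean log2 CPM of the list was 2.63 ± 0.39 in ConfettiNeg and 4.16 ± 0.30 in ConfettiPos, higher in 6 of 6 mice (exact permutation p = 0.00216, adjusted p = 0.00403). The camera call of the list (adjusted p = 1.98e-11) was lost with an estimated correlation (adjusted p = 0.114). The markers of macrophages described below moved with these genes between the groups.

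In the urea cycle and amino acid list, 11 of 24 tested genes were higher and 1 lower (13 and 1 adjusted over the list alone), with Got1, an aspartate aminotransferase, rising from 15.3 ± 2.06 to 44 ± 13.7 CPM. The camera call of this list (adjusted p = 0.00114) was lost with an estimated correlation (adjusted p = 0.121). In the cytochrome P450 and bile acid synthesis list, 5 of 11 were higher and 1 lower. Its Cyp27a1, a bile acid synthesis enzyme, rose from 2 ± 1.1 to 13.8 ± 3.13 CPM while Por, the electron donor of P450 enzymes, fell from 1119 ± 236 to 597 ± 49.3 CPM. Of the transporters, 5 of 9 were higher, among them the canalicular export pump Abcc2, which rose from 3.3 ± 1.18 to 26.9 ± 13.7 CPM. Of the glucose and lipid list, 6 of 21 were higher and 2 lower (7 and 4 adjusted over the list alone, and 5 and 4 with the animal as a block). Of the hepatocyte transcription factors, 4 of 19 were higher and 3 lower. Hnf4a, a regulator of hepatocyte genes (chromosome 2, 163348728 to 163414830), fell from 791 ± 80.1 to 552 ± 56 CPM (log2 fold change -0.52, SE 0.09, edgeR adjusted p = 0.000541). Onecut2 fell from 231 ± 29.9 to 157 ± 16.1 CPM. None of these 4 lists passed camera (adjusted p = 0.205, 0.0748, 0.699 and 0.63). The transporter list did pass without ConfettiNeg 2, 3, 4, 5 or 6 (adjusted p = 0.0333, 0.0471, 0.0267, 0.0356 and 0.0288), without ConfettiPos 2 or 6 (0.0173 and 0.0236) and with 8 libraries (0.0309), and its adjusted p ran from 0.0173 to 0.426 over its alternatives. The P450 list passed with no filter on low counts (adjusted p = 0.0365, range 0.0365 to 0.349). Counts in these short lists changed when single libraries were left out. The higher P450 genes numbered 3 without ConfettiNeg 4 or 6, and the higher glucose and lipid genes 3 without ConfettiPos 5. The higher transporters numbered 3 without ConfettiNeg 1 or 3 or ConfettiPos 1 or 3, and 2 without ConfettiPos 4 or 5. The higher transcription factors numbered 2 without ConfettiNeg 1, 3, 4 or 5, and 1 without ConfettiPos 1, 4, 5 or 6. The lower urea cycle genes numbered 0 without ConfettiNeg 2 or 4 or ConfettiPos 3 or 4.

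Biliary epithelial identity genes were lower in ConfettiPos in 18 and higher in 3 of 36 tested genes (20 and 3 adjusted over the list alone). Krt19, a keratin of duct cells (chromosome 11, 100031636 to 100039491), fell from 3922 ± 521 to 1573 ± 234 CPM (log2 fold change -1.32, SE 0.11, edgeR adjusted p = 1.44e-06). Krt7, another duct keratin (chromosome 15, 101308924 to 101328194), fell from 496 ± 105 to 190 ± 27.4 CPM, Cldn7 from 929 ± 52.8 to 538 ± 60 CPM and Cdh1, of E-cadherin, from 5623 ± 416 to 3905 ± 255 CPM. Spp1, of osteopontin, was at 33220 ± 2832 CPM in ConfettiNeg and 30320 ± 1980 CPM in ConfettiPos (edgeR adjusted p = 0.225). Sox9, of a duct transcription factor, was at 523 ± 268 and 657 ± 74.7 CPM (edgeR adjusted p = 0.503). Epcam, the gene of the selection marker, was at 1388 ± 926 CPM in ConfettiNeg and 909 ± 397 CPM in ConfettiPos (edgeR adjusted p = 0.477). Epcam lay at 251 and 204 CPM in ConfettiNeg 5 and 6, against 1587 to 2257 CPM in the other 4. Epcam was lower in ConfettiPos when the 4 libraries lowest in transcripts with GC-rich starts were left out (edgeR adjusted p = 0.00161). Those libraries were also the lowest in Epcam within each group, with ConfettiPos 1 and 6 at 385.5 and 443.4 CPM. Leaving them out, chosen after the data were examined, therefore removes much of the spread of the gene tested. Epcam was also lower with the GC slope as a covariate (edgeR adjusted p = 0.0271) and with that slope and the block (0.00711). Its adjusted p ran from 0.00161 to 0.81 over its alternatives. The list level fell from 9.63 ± 0.09 to 9.16 ± 0.07, lower in 6 of 6 mice (exact permutation p = 0.00216, adjusted p = 0.00403). Genes outside the lists matched on GC content and level were also lower, by a level difference of -0.15 (exact permutation p = 0.00216), and -0.32 of the biliary difference of -0.47 remained after theirs was subtracted. Camera placed the list lower (adjusted p = 3.96e-10), also with an estimated correlation (adjusted p = 0.0239), but not with an estimated correlation and the animal as a block (adjusted p = 0.115).

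**Figure D2:**
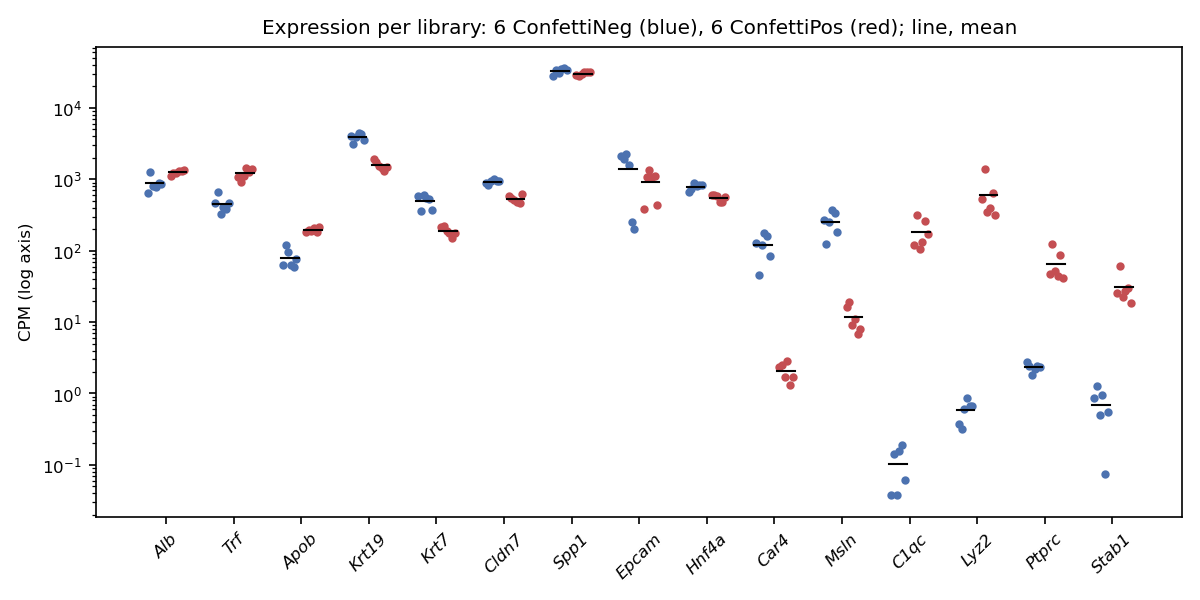
CPM per library on a log axis for 15 named genes, with 6 ConfettiNeg libraries in blue, 6 ConfettiPos libraries in red and the mean as a line. C1qc and Lyz2 lie under 1 CPM in each ConfettiNeg library and above 100 CPM in each ConfettiPos library.

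The 12 lower genes with the smallest p were Fam167a, Car4, Msln, Igfbp5, Car2, Mboat1, Serpinb1a, Krt19, Ndrg1, Gsta4, Plut and F3, with edgeR adjusted p from 9.27e-08 to 2.54e-06. Car4, a carbonic anhydrase anchored to the cell membrane (chromosome 11, 84848612 to 84856870), fell from 119 ± 48.8 to 2.07 ± 0.58 CPM. Plut, a noncoding RNA neighbouring Pdx1, had 254 counts in ConfettiNeg and 1 in ConfettiPos (ratio 282, 95% exact counting interval 50.1 to 11200). Its reads cannot be told from those of an overlapping partner. Mesothelium markers were lower in 5 of 8 tested genes and higher in 0, or 1 with the animal as a block. Msln, of mesothelin (chromosome 17, 25967587 to 25973352), fell from 256 ± 92.2 to 11.7 ± 4.84 CPM. The mesothelium level fell from 3.64 ± 0.36 to 1.37 ± 0.69 (exact permutation p = 0.00216, adjusted p = 0.00403). Camera placed it lower (adjusted p = 4.58e-05), also with an estimated correlation (adjusted p = 0.0413), but not with an estimated correlation and the block (adjusted p = 0.072). Genes of extrahepatic duct and mucous epithelium, a list written after the main results had been seen, fell along with these, from a level of 3.35 ± 0.87 to 0.67 ± 0.53 (exact permutation p = 0.00216). Of the biliary secretion and transport genes, 6 of 19 were lower and 3 higher (7 and 4 adjusted over the list alone). Car2, a cytosolic carbonic anhydrase, fell from 1506 ± 187 to 613 ± 84.6 CPM and the chloride channel gene Ano1 from 653 ± 121 to 374 ± 36.2 CPM. Of the progenitor and fetal liver genes, 5 of 14 were lower and 2 higher, with Ncam1 falling from 16.9 ± 6.22 to 3.29 ± 1.36 CPM. Neither list passed camera (adjusted p = 0.101 and 0.188), although the secretion list did with 8 libraries (adjusted p = 0.0434, range 0.0434 to 0.313), and the progenitor median was 0 beside a mean log2 fold change of -0.17.

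Kupffer cell and macrophage markers were higher in ConfettiPos in 16 of 16 tested genes, with a median log2 fold change of 9.92, or 9.6 with 2 genes of at most 3 counts in a group set at that floor. C1qc, of a complement C1q chain (chromosome 4, 136617115 to 136620376), rose from 0.10 ± 0.07 to 185 ± 86.1 CPM (log2 fold change 10.75, SE 0.45, edgeR adjusted p = 1.58e-08). Lyz2, of lysozyme (chromosome 10, 117113236 to 117118226), rose from 0.58 ± 0.20 to 601 ± 398 CPM. The 12 higher genes with the smallest p were Ccl3, C1qc, Lilrb4a, Lilrb4b, Ccl6, Rgs1, Spic, Mefv, Cd300c2, Lyz2, Wfdc17 and Tyrobp. Their means were all under 1 CPM in ConfettiNeg and 10.8 to 601 CPM in ConfettiPos (edgeR adjusted p from 1.58e-08 to 4.3e-08). Against 1 to 3 counts in ConfettiNeg, the ratios were 1930 for Spic (95% exact counting interval 662 to 9380), 1840 for Mefv (330 to 72700) and 2860 for Cd300c2 (512 to 113000). The macrophage level rose from -1.73 ± 0.26 to 6.25 ± 0.52 (exact permutation p = 0.00216, adjusted p = 0.00403). Camera placed it higher with the preset and with an estimated correlation (adjusted p = 1.62e-63 and 0.00218).

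Markers of other immune and vascular cells were also higher in ConfettiPos. These were 9 of 9 dendritic cell genes, 4 of 4 neutrophil genes, 15 of 17 T, NK and B cell genes (16 adjusted over the list alone) and 15 of 16 endothelial genes (15 higher and 1 lower adjusted over the list alone). The dendritic cell integrin gene Itgax rose from 0.03 ± 0.02 to 18.9 ± 13 CPM. Ptprc, of the leukocyte antigen CD45, rose from 2.33 ± 0.30 to 66 ± 32.5 CPM (log2 fold change 4.82, SE 0.30, edgeR adjusted p = 1.37e-07). Stab1, of a scavenger receptor of sinusoidal endothelium, rose from 0.70 ± 0.42 to 30.8 ± 15.3 CPM. The dendritic, T, NK and B cell and endothelial lists passed camera with an estimated correlation (adjusted p = 0.0239, 0.0413 and 0.0413). With the block as well, the T, NK and B cell list did not (adjusted p = 0.0502). The neutrophil list was too short to be tested by camera with all libraries and the default filter. Stellate cell and portal fibroblast genes were higher in 10 of 16 (11 adjusted over the list alone), with Pdgfrb rising from 2.14 ± 1.09 to 11.5 ± 8.43 CPM. Their camera call (adjusted p = 0.00114) was lost with an estimated correlation (adjusted p = 0.378). Erythroid genes were called in 0 of 5 by edgeR, also adjusted over the list alone, at an unadjusted p under 0.05 and by DESeq2 and voomWithQualityWeights, and camera did not call the list (adjusted p = 0.935). The globin gene Hba-a1 was at 9.73 ± 7.75 and 13.6 ± 13.2 CPM (edgeR adjusted p = 0.651). It lay at 37.9 CPM in ConfettiPos 2 against 1.53 to 18.7 CPM in the other ConfettiPos libraries. Its log2 fold change ran from -0.152 to 0.97 over its alternatives. Of neuroendocrine and enteric genes 0 of 4 passed edgeR, with 1 at an unadjusted p under 0.05, 1 by DESeq2 and 1 by voomWithQualityWeights, and 2 were lower with the block and 1 without ConfettiPos 2 or 3. Their level was 1.66 ± 0.81 in ConfettiNeg and 0.16 ± 0.95 in ConfettiPos (exact permutation p = 0.013, adjusted p = 0.0202), which did not pass with the libraries paired by mouse (exact sign-flip p = 0.0625, adjusted p = 0.0729).

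**Figure D3:**
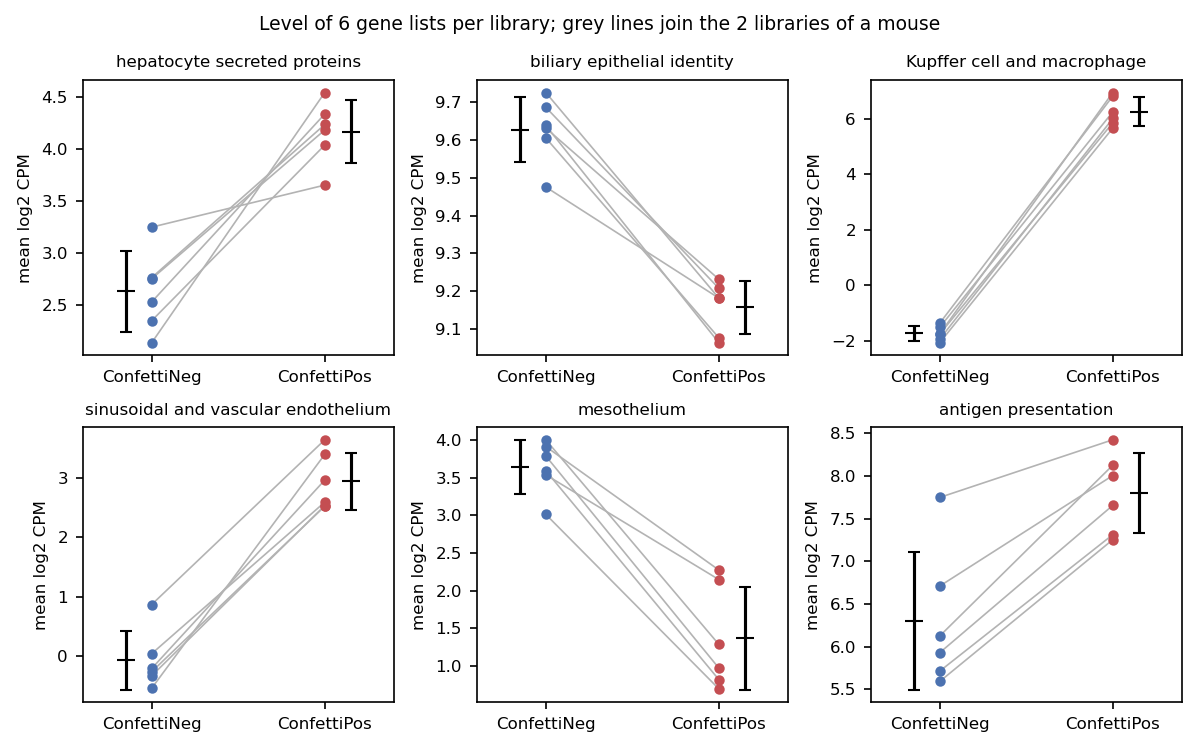
Mean log2 CPM of 6 gene lists per library, with grey lines joining the libraries of a mouse and bars for the mean and SD (n = 6); the axes do not start at 0. The hepatocyte, macrophage, endothelial and antigen presentation lists are higher and the biliary and mesothelium lists lower in ConfettiPos in each of the 6 mice.

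Immune response genes differed along with these macrophage and other leukocyte markers. Antigen presentation genes were higher in 7 of 19 (11 adjusted over the list alone), and in 17 with the animal as a block. Without ConfettiNeg 5 the count was 4, and without ConfettiNeg 6 it was 13. The MHC class II gene H2-Ab1 rose from 135 ± 199 to 1494 ± 880 CPM and H2-Eb1 from 32.2 ± 47.6 to 548 ± 348 CPM. ConfettiNeg 6 lay at 536 CPM of H2-Ab1 and 128 CPM of H2-Eb1, and without it the ConfettiNeg means were 55.1 ± 35.1 and 13.1 ± 9.5 CPM. The log2 fold change of H2-Ab1 was 3.46 with that library and 4.73 without it, and that of H2-Eb1 4.08 and 5.35. Interferon response genes were higher in 13 of 25 (15 adjusted over the list alone), with the antiviral gene Rsad2 rising from 19.5 ± 7.04 to 54.1 ± 11.7 CPM. Immediate early and dissociation stress genes were higher in 10 and lower in 1 of 26 (14 and 1 adjusted over the list alone), with Socs3, of an inhibitor of cytokine signalling, rising from 56.1 ± 9.92 to 165 ± 27.2 CPM. The lower stress genes numbered 0 without ConfettiNeg 2, 4 or 5 or ConfettiPos 1, 3, 4 or 5. Camera calls of the 3 lists (adjusted p = 0.00216, 0.000603 and 0.000326) were lost with an estimated correlation (adjusted p = 0.544, 0.507 and 0.324).

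The remaining lists were not called by camera with all libraries. Of YAP and TEAD targets, 5 of 22 were higher and 2 lower (7 and 2 adjusted over the list alone, and 9 and 2 with the block). Without ConfettiNeg 2, 10 were higher and camera called the YAP list (adjusted p = 0.0216, range 0.0216 to 0.544). Its F3, of tissue factor, fell from 7428 ± 606 to 3693 ± 481 CPM, and Axl, a receptor kinase also made by macrophages, rose from 6.72 ± 2.39 to 83.1 ± 40.5 CPM. Of the Notch pathway, 3 of 16 were higher and 1 lower, with the glycosyltransferase gene Lfng rising from 0.10 ± 0.11 to 3.7 ± 0.84 CPM (log2 fold change 5.17, and 5.85 without ConfettiNeg 3). Of Wnt pathway targets, 0 of 13 were higher and 2 lower, among them the ligand gene Wnt7a, which fell from 11.5 ± 6.05 to 2.06 ± 0.99 CPM. The median of the Wnt list was 0.02, while its mean was -0.42 and camera pointed down. Of cell cycle genes, 6 of 30 were higher and 2 lower (4 and 1 with the block), and the proliferation marker Mki67 rose from 4.09 ± 1.91 to 13.9 ± 4.66 CPM. Of cholesterol synthesis genes, 1 of 22 was higher and 2 lower. Of the mesenchymal and matrix genes, 8 of 23 were higher and 6 lower (9 and 6 adjusted over the list alone), with Vim, of vimentin, rising from 5.05 ± 2.02 to 44.8 ± 25.9 CPM. Of cilia genes, 6 of 32 were higher and 0 lower (2 and 0 adjusted over the list alone, and 4 and 1 with the block), and Pkhd1, of fibrocystin, rose from 312 ± 17.7 to 407 ± 33.7 CPM. Camera adjusted p-values of these 7 lists were 0.175, 0.184, 0.344, 0.344, 0.548, 0.344 and 0.803. By the exact permutation test of the levels, 19 of the 28 lists were higher and 3 lower past the adjusted threshold, among them the YAP, Notch and mesenchymal lists (each adjusted p = 0.00403) that camera did not call. This test compares each list with itself between groups and not with other genes. With the libraries paired by mouse, 15 lists were higher and 4 lower by the exact sign-flip test. Each of these lay at the smallest p that test can give (exact sign-flip p = 0.0312, adjusted p = 0.0461). They passed the adjustment only because so many lists share that p. The glucose and lipid, transporter, hepatocyte transcription factor, cell cycle and neuroendocrine lists no longer passed (each exact sign-flip p = 0.0625, adjusted p = 0.0729). The biliary secretion and Wnt lists passed only when paired, with level differences of -0.08 and -0.38 and a higher level in 0 of 6 mice (each exact sign-flip p = 0.0312, the smallest it can give, adjusted p = 0.0461, against 0.336 and 0.0554 unpaired). Markers of other cells moved with the YAP, Notch and mesenchymal lists, with the macrophage level going from -1.73 ± 0.26 to 6.25 ± 0.52, the dendritic cell level from -0.90 ± 0.35 to 4.07 ± 0.57 and the stellate and fibroblast level from 2.86 ± 0.66 to 4.33 ± 0.51. Some counts of these lists also changed when single libraries were left out. The higher cell cycle genes numbered 3 without ConfettiNeg 2 or 4 or ConfettiPos 5, and the lower ones 1 without ConfettiNeg 3 or 4 or ConfettiPos 1, 3 or 4. The higher cilia genes numbered 2 without ConfettiNeg 3 or 5 or ConfettiPos 1, and 3 without ConfettiNeg 2 or 4 or ConfettiPos 4 or 5, while 1 was lower without ConfettiNeg 3 or ConfettiPos 6. The higher Wnt genes numbered 2 without ConfettiNeg 2, and 1 without any other ConfettiNeg library or without ConfettiPos 1 or 2. The lower YAP genes numbered 1 without ConfettiNeg 1, 3, 4 or 5 or ConfettiPos 1, 2 or 6.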

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

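Of 334 groups of 6 libraries examined, over 134 named genes, 28 list levels and 5 library measures, 23 held a library whose distance to the nearest other, as a share of the group's range, exceeded Dixon's 95% critical value. Chance alone gives about 1 in 20 groups. ConfettiPos 2 was the outlying library in 8 of the 23.

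In ConfettiPos 2, Cyp7b1 was at 0.491 CPM against 1.84 to 3.08 in the others, Got1 at 71.3 against 34.7 to 43.4, Vim at 96.5 against 26.9 to 43, and Upk1b at 0 against 0.859 to 2.01. Csf3r was at 26.9 CPM in that library against 6.38 to 10.7, and Itgax at 44.9 against 11.2 to 17.7. Its mesenchymal and matrix level was 5.92 against 5.24 to 5.42, and its dendritic cell level 5.18 against 3.55 to 4.07 (mean log2 CPM).

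In the other ConfettiPos libraries, Wnt7a was at 0.245 CPM in ConfettiPos 3 against 1.56 to 2.76, and Mki67 at 4.9 in ConfettiPos 1 against 13.2 to 17.9. In ConfettiPos 5, Trbc2 was at 9.52 CPM against 3.65 to 5.13, and Pcsk1 at 0.901 against 3.19 to 3.87. Plut was at 0.0305 CPM in ConfettiPos 4 and at 0 in the others.

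Among the ConfettiNeg libraries, ConfettiNeg 2 stood apart in Cyp2d10, at 14.9 CPM against 4.74 to 6.13, and in Cdh1, at 4830 against 5580 to 6030. ConfettiNeg 6 was apart in Got1 (19.3 CPM against 13.4 to 15.3), in the interferon level (5.28 against 4.11 to 4.53) and in the stellate and fibroblast level (1.57 against 2.95 to 3.35). Kynu was at 0.761 CPM in ConfettiNeg 3 against 1.37 to 1.61, and Ddx58 at 29 in ConfettiNeg 4 against 33.6 to 35.3. Stab1 was at 0.075 CPM in ConfettiNeg 5 against 0.494 to 1.26. A single count set Mefv apart in ConfettiNeg 1 (0.0374 CPM) and Cd300c2 in ConfettiNeg 4 (0.0308 CPM), with the others at 0.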

How the results depend on the processing

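The alternatives with 8 libraries or a GC slope, and those for the count of list levels, were added after the data were examined. Counts of higher and lower genes stayed within 1.5 times their values of 2076 and 1661 under all alternatives except glmTreat, which gave 1047 and 372 because it tests a larger change. The animal as a replicate block gave 2028 and 1653 genes, with 1808 and 1486 shared with the unblocked fit. Leaving out 1 library gave 1775 to 2120 higher and 1311 to 1699 lower genes. Without the 4 libraries lowest in transcripts with GC-rich starts (ConfettiNeg 5 and 6, ConfettiPos 1 and 6), 1804 and 1373 genes were called. With the GC slope as a covariate the counts were 2351 and 1840, and with the block as well 2239 and 1856. No gene was called in the opposite direction under any alternative.

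An estimated correlation left 4 of the 10 higher lists and both of the 2 lower lists, since it allows for genes that vary together. Leaving out 1 library gave 10 to 13 higher lists and 2 lower lists. The hepatocyte secreted protein difference of 1.54 ran from 1.44 to 1.64, and the biliary difference of -0.47 from -0.52 to -0.45, when 1 library was left out. Both kept their side of the threshold under the other alternatives, with the exact sign-flip test of the replicate block at its smallest p, 0.03125. The 19 higher and 3 lower list levels became 15 and 4 with that test, and 17 to 19 and 3 to 4 when 1 library was left out.

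With glmTreat left aside, of 119 named genes past the threshold 103 kept it and their direction under all alternatives that tested them, and 114 to 119 did when 1 library was left out. The 16 others were Cyp2d10, Cyp7b1, Slc38a3, Aqp9, Nr1h4, Notch2, Wnt7b, Ccna2, Ccnb1, Mcm2, H2-DMa, Dhcr7, Rfx3, Ift46, Upk1b and Alb, and the cause was not tested. No named gene reversed where it was past the threshold in the main fit or the alternative. Hba-a1, Alas2, Pcsk1 and Hbb-bs, which were not past it, changed sign under at least 1 alternative. Their lowest log2 fold changes were -0.152, -0.058, -0.074 and -0.007. The block ended the calls of Cyp7b1 and Ift46 and added Tff3 and Vil1, and apart from these and the values given beside their results it changed no call of a named gene. Depth limits the genes under the floor of 3 counts in a group, whose folds are known only within wide intervals.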

Other observations

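Of 14 tested genes of extrahepatic duct, gallbladder and mucous epithelium, a list written after the main results had been seen, 9 were lower and 0 higher in ConfettiPos, Pdx1 and Dmbt1 left out. Without those, the list held 28 genes, and the others did not pass the filter on counts. Most tests in the paragraphs on explanations were chosen only after the result was seen, namely the comparison of cell type medians, the hepatocyte tests, the spread of the biliary genes, the levels corrected by genes matched on GC, the pancreas and intestine tests and both tests of library differences. The corrected levels took the place of GC tests on called genes alone and with the GC slope as a covariate, which could not decide because those genes were chosen for being lower and because the slope differed by only 0.0141 log2 per 10% of GC between the groups (exact permutation p = 0.745). The genes named in this paragraph were chosen after their values were seen. Muc6, of a gel-forming mucin, fell from 16.4 ± 11.2 to 0.364 ± 0.404 CPM (SD, n = 6, edgeR adjusted p = 0.000551; 0.22 ± 0.217 without ConfettiPos 6), and Tff2, of a mucosal trefoil peptide, from 55.4 ± 15.7 to 8.91 ± 4.06 CPM (edgeR adjusted p = 2e-05). Vsig2 fell from 13.4 ± 7.28 to 0.612 ± 0.402 CPM and Agr2 from 2.88 ± 2.24 to 0.0664 ± 0.0898 CPM (0.0339 ± 0.0467 without ConfettiPos 1). Pdx1, a transcription factor of pancreas and extrahepatic duct, had 630 counts in ConfettiNeg and 0 in ConfettiPos, at least 233-fold lower against a floor of 3 counts over the group. Dmbt1, of a mucosal glycoprotein, was at 3530 ± 3150 and 153 ± 313 CPM, with 790 CPM in ConfettiPos 3 and a mean of 25.9 ± 23.9 CPM without it. Its log2 fold change was -4.53 with all libraries (edgeR adjusted p = 0.0267), -7.10 without ConfettiPos 3, and not past the threshold without ConfettiPos 1 (adjusted p = 0.0505, range 8.16e-05 to 0.0505 with 1 library left out). The level of the list was 3.35 ± 0.87 in ConfettiNeg and 0.67 ± 0.53 in ConfettiPos (exact permutation p = 0.00216).

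Antigen presentation and interferon levels were highest in both libraries of mouse 6 within their groups, at 7.749 and 8.425 for antigen presentation and 5.277 and 5.873 for interferon response (mean log2 CPM). ConfettiPos 3 had 129 genes at 0 counts whose mean in the other ConfettiPos libraries was at least 1 CPM, against 21 to 82 in the other ConfettiPos and 1 to 18 in the ConfettiNeg libraries.

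The macrophage correlation, the extrahepatic list test and the splits of the libraries were written before their results. Of the 462 splits of the 12 libraries, 69 were run, the real one included. Counting either direction, 1 gave as many higher genes (2076, highest other 140) and 1 as many lower genes (1661, highest other 140). Splits that mix the groups put the difference between the groups into the spread within each side, which lowers their counts. The real split was therefore likely to come out highest, and these counts cannot exclude chance. Among the 32 splits that part all 6 mice, the highest other gave 40 genes. For the lists, 13 of the 69 splits gave at least 10 lists and 63 gave at least 2, with 15 as the highest other. The other splits with at least 10 lists kept most libraries of a group together, so they carried part of the real difference. They therefore cannot decide on chance for the lists. The count of lists called by camera with the preset correlation is not taken as evidence by itself.

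Of the macrophage markers, 16 of 16 were higher in ConfettiPos. A lower share of cholangiocytes that raised all other cell types alike is argued against by medians that differ by 9.42 on the log2 scale between macrophage and erythroid genes, with quartiles of 8.65 to 10.57 and 0.49 to 0.52. These quartiles are spreads over genes, only 5 of them erythroid, and not over libraries. Over libraries the erythroid level was 0.84 ± 1.13 in ConfettiNeg and 1.02 ± 1.68 in ConfettiPos, and the macrophage level -1.73 ± 0.26 and 6.25 ± 0.52. Across the 6 ConfettiPos libraries the macrophage markers varied together, with a median pairwise correlation of 0.753 against a 95th percentile of 0.191 in 2000 random sets of matched level. Macrophages or their RNA in the ConfettiPos libraries may therefore be a source, although EpCAM selection would be meant to remove them; of the 16 markers 3 reached 1 CPM in ConfettiNeg, 0 are in another list, and the most abundant, Lyz2, averaged 601 CPM in ConfettiPos. The gates are not given in the sources used here, so autofluorescent cells or doublets taken as reporter-positive stay open and were not tested, and with them what share of ConfettiPos RNA came from traced cells.

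Of the hepatocyte secreted protein genes, 31 of 37 were higher in ConfettiPos. Hepatocyte RNA as the source of the Alb and Trf difference is argued against by 8 other abundant hepatocyte transcripts. These rose together by 1.86% of the CPM by which Alb and Trf rose (0.73% to 4.2% per library), with Apoa1 at 5.22 ± 2.59 CPM beside 1258 CPM of Alb. The 8 were chosen after the result was seen and leave out Apob. Its libraries lay at 58.4 to 120.9 CPM in ConfettiNeg and 184.1 to 215.2 CPM in ConfettiPos. Adding Apob would raise the share, so the argument covers these 8 only. The 19 members under 10 CPM varied together (median correlation 0.384, 95th percentile of random sets 0.127). Traces of hepatocyte RNA may account for these, but genes expressed together in the traced cells would also vary together. The correlation therefore cannot tell these 2 sources apart. RNA carried in with macrophages, which needs the list level to rise with the macrophage level, was not decided by the 6 ConfettiPos libraries (Pearson r = -0.45, exact permutation p = 0.386, Spearman rho = -0.2, exact permutation p = 0.714, both 0.714 after adjustment over 2 tests, r = -0.70 to -0.03 with 1 library left out and 0.12 without the 2 farthest) and stays open. Expression of Alb, Trf and the members under 10 CPM in traced cells themselves stays open as a hypothesis that was not tested.

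In the biliary identity, mesothelium and extrahepatic lists, 18 of 36, 5 of 8 and 9 of 14 tested genes were lower in ConfettiPos. Dilution by RNA of other cells that lack these genes lowers all biliary genes by 1 factor. As the only cause it is argued against by the spread of their differences in mean log2 CPM. The interquartile range was 0.72, against at most 0.29 in 100 splits with 3 libraries of each group on both sides. The test cannot decide on dilution by cells that express some of these genes, or on dilution as a part of the difference. Genes outside the lists matched on GC and level were lower too, with a level difference of -0.15 (exact permutation p = 0.00216), so dilution as a part stays open. After the level of genes outside the lists matched on GC of the first 200 bases and on level was subtracted in each library, 111.1% of the mesothelium and 116.1% of the extrahepatic difference remained. The matched genes were higher in ConfettiPos, by 0.25 for mesothelium and 0.43 for extrahepatic (each exact permutation p = 0.00216). Of the 14 tested extrahepatic genes, 12 had a GC value. This argues against a GC effect there, although an opposite effect of expression level, which was matched too, could hide one. Of the biliary difference 67.7% remained (-0.32 of -0.47, exact permutation p = 0.00216, exact sign-flip p = 0.0312 with the libraries paired by mouse). The part shared with the matched genes cannot be assigned to GC, since they were matched on level too. The slope on GC content was higher in ConfettiPos by only 0.0141 log2 per 10% of GC (exact permutation p = 0.745). A GC effect on part of the biliary difference is therefore not shown, though not excluded. Pancreas or intestine tissue is argued against by 13 of 14 of their transcripts under 1 CPM in ConfettiNeg, although Cela1 alone, at 13.8 ± 9.6 CPM, met the bound first set as pointing to such tissue, and the test over all 14 was added after that was seen because 1 transcript cannot stand for a tissue that brings them all. The extrahepatic list was lower by camera (p = 4.25e-08, and p = 0.0228 with an estimated correlation, or 0.0568 without ConfettiPos 2). A larger share of extrahepatic or large duct epithelium in ConfettiNeg may therefore contribute. Only 14 of the 28 list genes were tested, and the others had means of 0 to 1.82 CPM in ConfettiNeg. The reading thus rests on the detected members and not on all genes of such epithelium. A difference in expression between traced and untraced cells of the same ducts stays open and was not tested.

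A component of the differences between libraries of the same group held 50.4% of that variance, and it lowered Epcam in ConfettiNeg 5 and 6 and ConfettiPos 1 and 6. Across 6835 of 7183 genes, which are not independent replicates, its loading fell with the GC content of the first 200 bases of the transcript (Spearman -0.31, against 0.2 for the last 500 bases) and with transcript length (Spearman -0.21). The partial Spearman correlation was -0.28 with that GC content given length and -0.16 with length given that GC content. In 2 of 6 mice the libraries had opposite signs on this component.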
